A study of Mus musculus with 12 samples.

How the data were processed

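RNA was measured in 12 libraries of mouse retina at embryonic day 15.5, each from a pool of 12 retinas of C57BL/6 strain background per the labels. The 4 groups were wildtype males, mutant males, wildtype females and mutant females, with 3 libraries in each, numbered 4, 5 and 6 in the labels. Mutant retinas carried floxed Tbr2 alleles and Six3-Cre, which expresses Cre recombinase in the developing eye field. Tbr2 is listed under its gene symbol Eomes. Per the series design text, retinas of several litters were pooled, so the p-values measure the spread between pooled libraries and not the spread between single embryos.

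Per the submitters' processing notes, bases were called with CASAVA, reads were aligned to mm10 with STAR 2.5, genes were counted with HTSeq 0.6.1 and groups were compared with DESeq2. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes on opposite strands therefore cannot be told apart, and genes that share reads with paralogs or pseudogenes are uncertain.

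The authors deposited 3 tables, of both sexes, of males and of females. Per the file headers, each held raw read counts per gene and library, and these counts were whole numbers with no normalization. A normalised signal column per library equalled the deposited count divided by a constant of that library, as a size factor does. The deposited FPKM values were counts scaled by the listed gene length and by the total of the library. The log2 fold changes deposited by the authors compared mutant with wildtype and were smaller in size than the ratios of the group means. The p-values and adjusted p-values deposited by the authors came from their DESeq2 comparison, per the file headers and the processing notes. Listed genes numbered 19954 in the tables of both sexes and of females, which held the same genes, and 20379 in the table of males. Each listed gene had at least 1 read. The signal, FPKM and deposited log2 columns entered no test here.

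Tests used the deposited counts with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes with low counts were removed by filterByExpr on the groups compared, and the quasi-likelihood test was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparison of both sexes had genotype and sex as terms over 12 libraries. Males and females were also tested alone over the 6 libraries of each sex. The interaction of genotype and sex, and female against male wildtype, used all 12 libraries. CPM values were counts over the total of the library without TMM scaling, and are given as mean ± SD. Standard errors were the size of the log2 fold change over the square root of the F statistic of the same fit. They restate that test and are no separate measure of spread.

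Before the data were examined, the comparisons, the tests, the alternatives, 22 gene lists and the rule for named genes were fixed. The rule named Eomes first, then up to 10 genes per direction with the largest change among those past the threshold, with a mean of at least 1 CPM and no overlap of mutant and wildtype libraries within each sex. It also named members of the lists past the threshold, up to 5 genes per direction in each sex, the 5 genes with the smallest interaction p, and the sex-linked list. Predicted genes and pseudogenes were skipped among the largest changes. Genes named outside this rule were chosen after their values were seen.

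The 22 lists covered intrinsically photosensitive retinal ganglion cells (ipRGC), all ganglion cells, other ganglion cell subtypes, progenitors, neurogenic precursors, amacrine cells, horizontal cells, photoreceptors, proliferation, axon guidance, excitability and synapses, apoptosis and stress, immediate early genes, and hypoxia and glycolysis. They also covered pigment epithelium, lens, blood, vessels and mesenchyme, microglia, surface ectoderm, ciliary margin and stalk, and sex-linked genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. These tests took the counts with the dispersions estimated by edgeR. Log2 CPM with a prior count of 2 served the principal components and the correlations between libraries.

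Each test was checked on simulated counts with 200 changed genes of at least 1 CPM. Counts were drawn separately for each gene, without the differences between sets of libraries or correlation between genes seen in the data. The shares recovered therefore describe such simulated counts and can differ in these libraries. With 200 changed genes the Benjamini-Hochberg threshold is also easier to reach than where few genes pass, as in the real fits. In the fit of both sexes over 15301 genes, 61.2% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. For males, over 14720 genes, the shares were 5.97%, 53.7% and 95.5%. For females, over 14780 genes, they were 34.3%, 80.6% and 92.4%. The interaction over 15299 genes gave 7.46%, 43.3% and 92.4%, and female against male wildtype over 15287 genes gave 26.9%, 65.7% and 93.9%. False calls among unchanged genes numbered 2 for both sexes, 9 for males and 7 for females. They numbered 3 for the interaction and 3 for female against male wildtype. In the list test, 20 of 20 simulated lists of 13 genes changed 1.3-fold were recovered, with 2 false calls among 20 unchanged lists.

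Totals per library lay between 18514607 and 27072825 counts. Pairs of libraries within a group differed by a chi-square of at least 6.75 per gene, so each was counted as a separate library. Same-numbered wildtype and mutant libraries were compared by the correlation of their deviations from the group means. In females these correlations were 0.236, 0.253 and 0.152, all above the bound for pairing, and the fit with the replicate number as a block is given beside the result. Female pairs with unlike numbers gave -0.405 to 0.213. The highest, wildtype 6 with mutant 4, lay above the 0.152 of number 6, so the pairing of number 6 is uncertain. In males they were -0.233, 0.0310 and 0.334, and no pairing was assumed.

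Alternatives were DESeq2 1.42.0, its size factors in edgeR, limma voom, other filters on low counts, stricter thresholds, the replicate block, no sex term, a fit of 4 groups, and each library left out in turn. After the data were seen, further alternatives were added. They were a term for 2 sets of libraries parted at 100 CPM of mt-Nd6, fits within each set, that term with mutant male 6 left out, robust empirical Bayes, voom with sample quality weights, Cryaa as a covariate, the 3 libraries highest in Cryaa left out, and an estimated correlation for the lists in the fits with the block, within the sets or with a library left out. Alternatives meant for files without counts did not apply. A test of a gene list added after the data were seen is not reported here.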

Results

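Gene expression was measured by RNA sequencing in 12 libraries of embryonic mouse retina, with 3 pools per genotype and sex. Total counts were 19237301, 25596000 and 23824001 in wildtype males 4, 5 and 6, and 20984568, 19326223 and 18514607 in mutant males 4, 5 and 6. Wildtype females 4, 5 and 6 had 27072825, 19681999 and 20021234 counts, and mutant females 4, 5 and 6 had 22545610, 23401692 and 20600860. Between 16903 genes, in mutant male 6, and 19242 genes, in mutant female 4, had at least 1 read. The first principal component held 33.1% of the variance, and mutant male 6 lay farthest out on it at 71.3. The mitochondrial transcript mt-Nd6 stood at 373 to 484 CPM in 5 libraries (wildtype male 5, mutant male 4, wildtype females 4 and 6, mutant female 4) and at 9.70 to 48.4 CPM in the other 7. Each genotype and sex held libraries of both kinds.

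Eomes, the T-box transcription factor gene targeted in the mutant, was lower in every mutant library than in any wildtype library. Its level was 56.8, 76.1 and 65.5 CPM in wildtype males 4, 5 and 6, and 24.9, 21.2 and 27.4 CPM in mutant males. In wildtype females 4, 5 and 6 it was 53.8, 53.4 and 64.6 CPM, and in mutant females 9.62, 15.2 and 16.1 CPM. The counts cover the whole gene (ENSMUSG00000032446, protein coding, mm10 chromosome 9, 118478212 to 118486132), including any exons outside the deleted part.

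The first comparison asked which genes differed between mutant and wildtype retina over both sexes. Eomes fell from 61.7 ± 8.77 to 19.1 ± 6.65 CPM (SD, n = 6 each). Trhde, which encodes an enzyme that degrades thyrotropin-releasing hormone, fell from 12.4 ± 1.77 to 5.81 ± 1.16 CPM. Synm, which encodes the intermediate filament protein synemin, fell from 73.4 ± 9.35 to 47.6 ± 9.04 CPM. Wnt4, a secreted Wnt ligand gene, fell from 0.924 ± 0.223 to 0.0940 ± 0.117 CPM, or from 13 to 27 counts per wildtype library to 0 to 6 per mutant library. Wnt4 lay under the level set for named genes and was chosen after its values were seen. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were -1.76 for Eomes (SE 0.15, adjusted p = 0.000484) and -1.10 for Trhde (SE 0.14, adjusted p = 0.0142). The same edgeR test gave -0.63 for Synm (SE 0.09, adjusted p = 0.0491) and -3.34 for Wnt4 (SE 0.47, adjusted p = 0.0361). Leaving out each library in turn, Wnt4 ran from -4.09 to -3.11. In 6 of 6 mutant libraries each of these 4 genes was below all wildtype libraries of the same sex. Trhde lies on mm10 chromosome 10 from 114398823 to 114802307, Synm on chromosome 7 from 67730161 to 67759742, and Wnt4 on chromosome 4 from 137277489 to 137299726, all protein coding.

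These 4 were the genes past the threshold among 15467 tested, 0 of them higher in mutants, and 451 genes had an unadjusted p under 0.05 where 773 would by chance. DESeq2 called 15 genes and limma voom 5. With the replicate number as a block, which did not pair the males, edgeR called 1 gene, Eomes. For 98 genes (0.634%) mutant and wildtype libraries did not overlap in either sex, against 1% by chance, and 61 of them (0.394%) went the same way in both sexes, against 0.5%. In the authors' deposited table of both sexes, 15 genes had an adjusted p under 0.05, 4 higher and 11 lower. Within the 5 libraries high in mt-Nd6 the log2 fold change of Eomes was -2.12, and within the other 7 it was -1.50. Trhde was at -0.98 and -1.10, Synm at -0.90 and -0.45, and Wnt4 at -3.56 and -3.27 in these sets. The high set gave 3 genes past the threshold (Eomes, Synm and Espn) and the other set 3 (Eomes, RP24-68F22.7 and Tuba1c), so Trhde and Wnt4 passed in neither set and Synm in the high set alone. The count of 4 was 1 without wildtype male 5, wildtype male 6, mutant male 5, wildtype female 4 or mutant female 6, and 2 without wildtype male 4, mutant male 4 or wildtype female 5. Eomes was called in each of the 12 fits that left out 1 library, Trhde in 7, and Synm and Wnt4 in 2 each, those without mutant male 6 or mutant female 5. With the 3 libraries highest in Cryaa, a lens gene, left out (mutant female 5, mutant male 5 and wildtype male 5) Eomes lost its call at a log2 fold change of -1.71 (SE 0.21, 9 libraries, edgeR adjusted p = 0.131, with 2.53e-26 to 0.131 over its 29 alternatives).

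**Figure D1:**
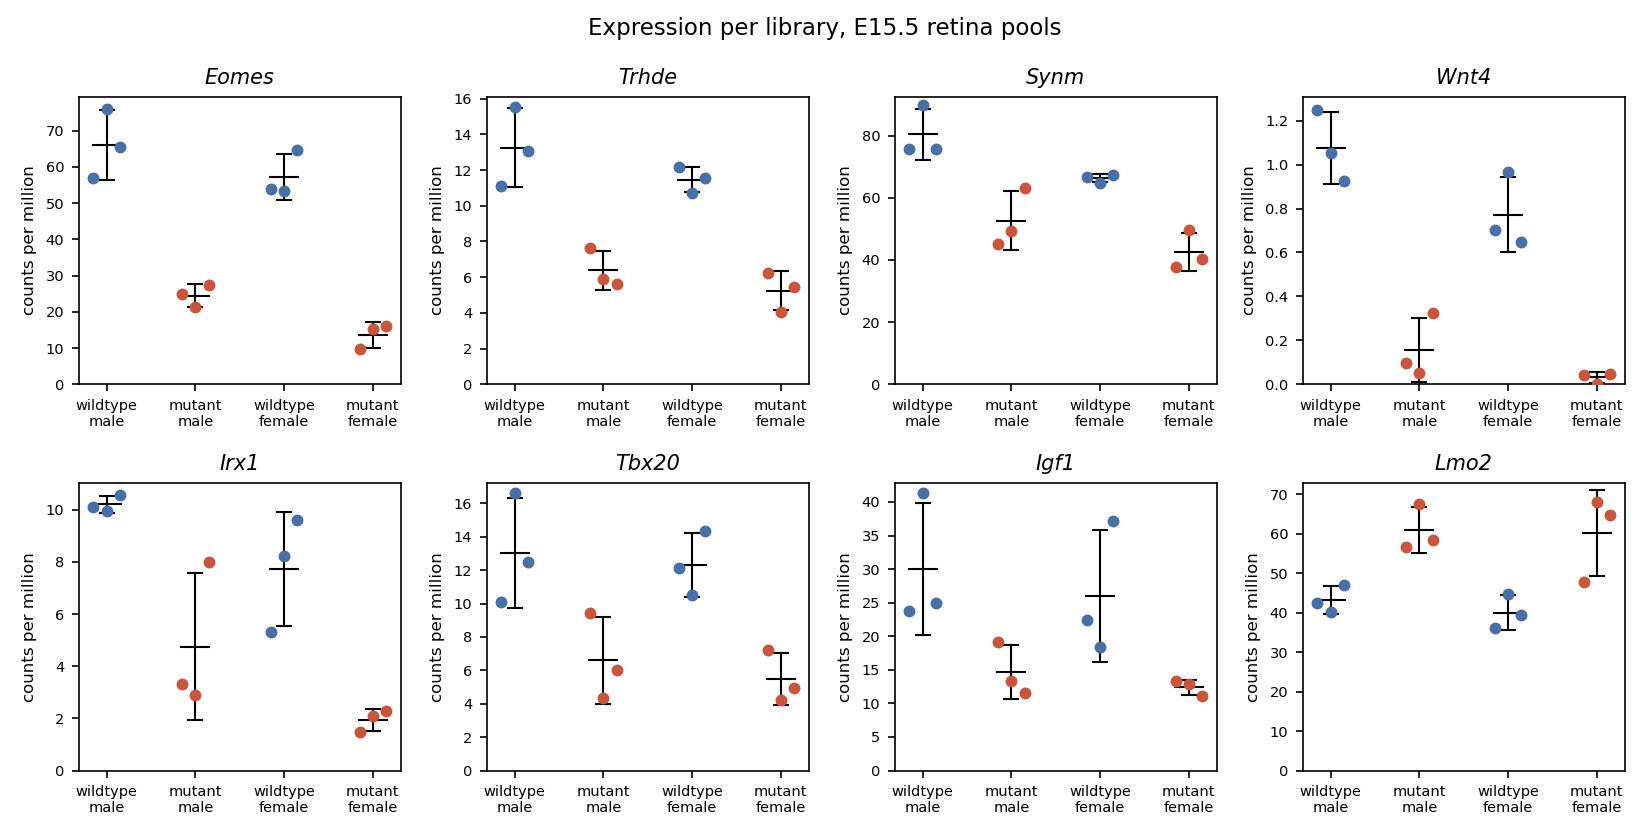
Expression in CPM (vertical axes, from 0) of 8 genes in each library of the 4 groups. Points are libraries, and bars are the mean ± SD of 3 libraries. Eomes lies between 53.4 and 76.1 CPM in wildtype and between 9.62 and 27.4 CPM in mutant libraries.

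The list of genes of intrinsically photosensitive retinal ganglion cells, the melanopsin-expressing cells named in the title of the series, fell as a group. Of 13 tested members 9 were lower and 4 higher, with a median log2 fold change of -0.25. This median was -0.43 without mutant female 5, -0.41 without mutant male 5, and -0.39 without either mutant female 6 or wildtype female 4. Irx1, a homeobox gene, stood at 8.96 ± 1.95 CPM in wildtype and 3.34 ± 2.37 CPM in mutants (n = 6 each). Tbx20, a T-box gene, was at 12.7 ± 2.44 and 6.03 ± 2.01 CPM, and Igf1, encoding insulin-like growth factor, at 28.0 ± 9.07 and 13.6 ± 2.90 CPM. Lmo2, encoding a LIM-domain protein, went the other way, at 41.6 ± 3.90 and 60.5 ± 7.87 CPM. The list passed camera with an adjusted p of 9.76e-06, with an adjusted p of 0.0257 with an estimated correlation, and with an adjusted p of 0.0192 by fry. Adjusted over the list alone, 5 members passed the edgeR test (Lmo2, Irx1, Igf1, Tbx20 and Adcyap1), and over all genes tested 0 did, while 7 had an unadjusted p under 0.05. Over all genes, edgeR with Benjamini-Hochberg adjustment gave Irx1 -1.53 (SE 0.27, adjusted p = 0.148), Tbx20 -1.08 (SE 0.21, adjusted p = 0.223) and Lmo2 0.54 (SE 0.09, adjusted p = 0.0849). DESeq2 called 4 members, Igf1, Irx1, Lmo2 and Tbx20. Opn4, the melanopsin gene, chosen after its values were seen, was at 1.61 ± 0.269 and 1.01 ± 0.686 CPM, with a log2 difference of -0.71 (SE 0.35) that did not pass. The difference of Opn4 ran from -1.07 without mutant male 6 to -0.53 without mutant female 4. The median of the list was -0.55 within the 5 libraries high in mt-Nd6 and -0.17 within the other 7, with 15 and 14 members tested. It passed camera in both sets at the preset correlation (adjusted p = 2.61e-08 and 0.0277) and in neither with an estimated correlation (adjusted p = 0.577 and adjusted p = 0.714). It also did not pass with an estimated correlation without mutant male 4 (adjusted p = 0.161) or without mutant female 4 (adjusted p = 0.120). The same loss occurred with the replicate number as a block. Within the high set 8 other lists were called lower at the preset correlation: neurogenic precursors, amacrine cells, photoreceptors, axon guidance, excitability and synapses, hypoxia and glycolysis, lens and blood. With an estimated correlation these 8 had an adjusted p of 0.577 to 0.592. In these sets Irx1 was at -1.94 and -1.30, Tbx20 at -0.84 and -1.14, Igf1 at -1.13 and -0.81, Lmo2 at 0.41 and 0.54, and Opn4 at -1.76 and -0.25, none past the edgeR threshold over all genes.

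The 21 genes shared by ganglion cells did not pass as a list (camera adjusted p = 0.976), with 15 lower, 6 higher and a median log2 fold change of -0.04. Adjusted over the list alone, Ebf3 passed at 0.20 (SE 0.05), with 0.19 and 0.22 within the sets high and low in mt-Nd6. This call was lost within both sets and without wildtype male 4, wildtype male 6, mutant male 4, wildtype female 5, wildtype female 6, mutant female 4 or mutant female 5, and without mutant female 6 the list had 2 such calls. Pou4f2, a ganglion cell transcription factor gene, was at 148 ± 10.1 CPM in wildtype and 139 ± 15.4 CPM in mutants, and Isl1 at 163 ± 5.13 and 159 ± 13.9 CPM, both chosen after their values were seen. Their log2 differences were -0.09 and -0.04, and turned to 0.0116 and 0.0500 within the high set, none of them past the threshold. The remaining 20 lists did not pass camera at the preset correlation either. All 15 tested lens genes were higher in mutants, with a median of 1.48 (adjusted p = 0.0525, and adjusted p = 0.724 with an estimated correlation). The lens list passed without wildtype male 5 (median 3.02), and without mutant male 6, wildtype female 4, wildtype female 5, mutant female 4 or mutant female 6 (medians of 1.48 to 1.85), with an adjusted p of 0.446 to 0.752 with an estimated correlation in these fits. Without mutant female 5 its median was -0.40 and camera pointed down (adjusted p = 0.420). The lens gene Cryaa ranged from 0.918 CPM in mutant male 6 to 907 CPM in mutant female 5. Lens genes were called lower within the 5 libraries high in mt-Nd6 and higher within the other 7 at the preset correlation (adjusted p = 0.577 and adjusted p = 0.714 with an estimated correlation). Of 13 amacrine genes 10 were lower, with a median of -0.12 (adjusted p = 0.0525, and adjusted p = 0.602 with an estimated correlation). The amacrine list passed without wildtype male 4, mutant male 6, wildtype female 4, wildtype female 5, mutant female 5 or mutant female 6, with an adjusted p of 0.00503 to 0.0276, and of 0.404 to 0.590 with an estimated correlation.

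Camera's adjusted p was 0.0773 for microglia, with 8 of 9 genes higher, 0.110 for progenitors and 0.127 for axon guidance. Without wildtype female 4 these 3 lists passed (adjusted p = 0.0174, 0.0423 and 0.0362), as did axon guidance without wildtype male 5 (adjusted p = 0.00484) and blood without mutant male 6 (adjusted p = 0.0314). With an estimated correlation the same fits gave an adjusted p of 0.169, 0.507 and 0.627 for the 3 lists, of 0.446 for axon guidance and of 0.479 for blood. Camera gave 0.137 for excitability and synapses and for ciliary margin and stalk, 0.157 for immediate early genes, 0.185 for hypoxia and glycolysis and 0.240 for apoptosis and stress. Blood gave 0.337, sex-linked genes 0.351, horizontal cells 0.632, and other ganglion cell subtypes and photoreceptors 0.741 each. Surface ectoderm gave 0.933, and neurogenic precursors, proliferation, pigment epithelium, and vessels and mesenchyme 0.935 each. Pigment epithelium had a median of 0.01 where camera pointed down, neurogenic precursors a mean of -0.02 and vessels and mesenchyme a median of -0.02 where it pointed up. At the preset correlation the count of 1 list was 2 without wildtype male 4, mutant female 4 or mutant female 5, and 3 without wildtype male 5, wildtype female 5 or mutant female 6. It was 4 without mutant male 6 and 6 without wildtype female 4, and the ipRGC list was called in all 12 of these fits.

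**Figure D2:**
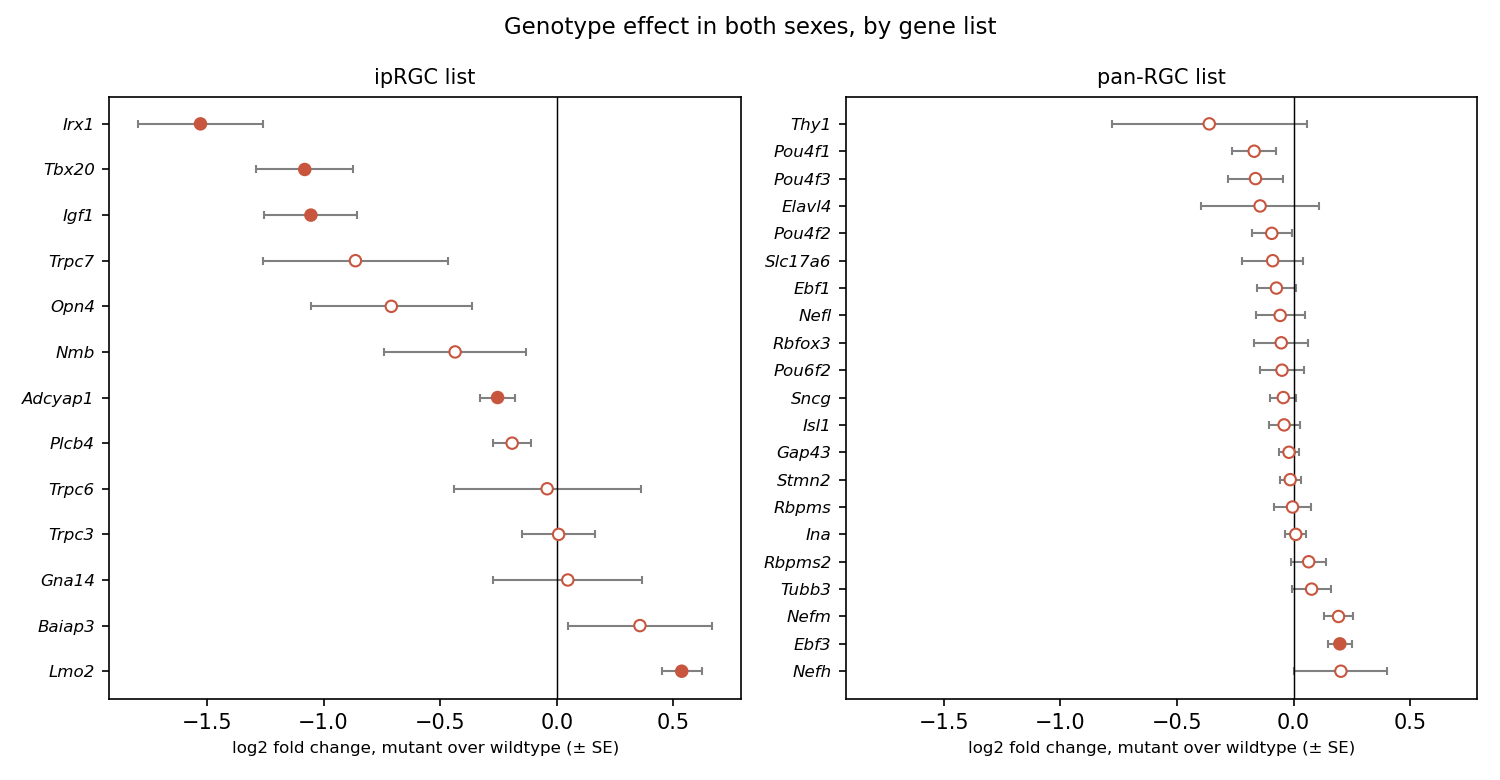
Log2 fold changes of mutant over wildtype in both sexes (horizontal axes) with bars of 1 SE, for the ipRGC list and the list shared by ganglion cells. Filled points passed the edgeR test adjusted over the list alone, 5 of 13 genes on the left and 1 of 21 on the right.

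In males alone, Eomes was at 66.1 ± 9.66 CPM in wildtype and 24.5 ± 3.10 CPM in mutants (n = 3 each). Its log2 fold change of -1.43 (SE 0.16) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.377). Trhde stood at -1.05 (SE 0.21) and Prkcq, a protein kinase C gene chosen after its values were seen, at -1.37 (SE 0.21), neither past the threshold. The edgeR test called 0 of 14950 genes, with 217 at an unadjusted p under 0.05, and limma voom called 0. DESeq2 called 6, namely Eomes, Gm3756, Prkcq, RP24-68F22.7, Trhde and Tuba1c. In the authors' deposited table of males 6 genes passed, 3 higher and 3 lower. For 806 genes (5.39%) the groups did not overlap, against 10% by chance. Within the 4 male libraries low in mt-Nd6 Eomes was at -1.32, and the other set held 1 library of each genotype, too few for a test. With a term for the library set, edgeR called 2 genes, Eomes and RP24-68F22.7.

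In females alone, Eomes fell from 57.3 ± 6.32 to 13.6 ± 3.49 CPM (n = 3 each). It was the 1 gene past the threshold among 14956 tested (log2 fold change -2.08, SE 0.18, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0271). Irx1 was at 7.71 ± 2.18 CPM in wildtype and 1.95 ± 0.428 CPM in mutants, with a log2 fold change of -1.98 that did not pass (edgeR adjusted p = 0.546). With the replicate number as a block, edgeR called 2 genes, Eomes and Irx1. DESeq2 called 9 genes and limma voom 1, and in the authors' deposited table of females 9 genes passed, 1 higher and 8 lower. For 1210 genes (8.09%) the groups did not overlap, against 10% by chance. The call of Eomes was lost, with 0 genes by edgeR, without wildtype female 4, wildtype female 5, mutant female 5 or mutant female 6, where 333, 440, 373 and 480 genes had an unadjusted p under 0.05, against 394 in the full fit. Without wildtype female 6 the test called 2 genes, Cacna1i and RP24-68F22.7, and not Eomes. Over the 6 fits that left out 1 female library the log2 fold change of Eomes was -2.20 to -1.89. Within the sets of libraries high and low in mt-Nd6 Eomes was at -2.60 and -1.76, and Irx1 at -2.31 and -1.89. Each set held 3 female libraries, with mutant female 4 and wildtype female 5 the only ones of their genotype there, too few to read calls from.

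The interaction asked whether the genotype effect differed between the sexes. For Eomes the effect in females minus that in males was -0.64 (SE 0.25), which did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (unadjusted p = 0.0264, adjusted p = 1.0). Within the libraries high in mt-Nd6 it was -0.97, and within the others -0.43. The genes with the smallest p were Gm13123 at 3.02, Gm13410 at 1.53, 4930570G19Rik at -1.73, the ribosomal protein gene Rps23 at 0.63 and the mitochondrial ribosomal protein gene Mrpl12 at 0.54. Gm13123 and Gm13410 are annotated as pseudogenes, and with Rps23 they can share reads with related sequences. The edgeR test called 0 of 15467 genes, with 267 at an unadjusted p under 0.05, and DESeq2 and limma voom each called 0. Within the libraries high in mt-Nd6 it called 2 genes, Cwc22 and Malat1, in a fit where 3 of the 4 groups held 1 library, assumed to vary like the others.

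Female and male wildtype retina were compared as a check of the labels. Xist, the noncoding RNA that acts in X inactivation, was at 1720 ± 184 CPM in females and 0.173 ± 0.183 CPM in males (n = 3 each). Its log2 fold change was 13.36 (SE 0.50, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.32e-08), and it was the 1 gene past the threshold among 15467. Eif2s3x, Kdm6a, Ddx3x and Kdm5c, X-linked genes that escape inactivation, were at 0.65, 0.74, 0.47 and 0.28, none past it. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were absent from the table of both sexes and could not be tested here. In the table of males Ddx3y ranged from 19.6 to 65.0 CPM and Uty from 9.67 to 34.0 over the 6 libraries. Kdm5d ranged there from 30.4 to 51.2 CPM and Eif2s3y from 12.1 to 44.6. Without mutant male 6, and with DESeq2, 2 genes were called, Xist and Eif2s3x. Within the set high in mt-Nd6 the test called 4 genes, with wildtype male 5 the lone male of that genotype and assumed to vary like the others.

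**Figure D3:**
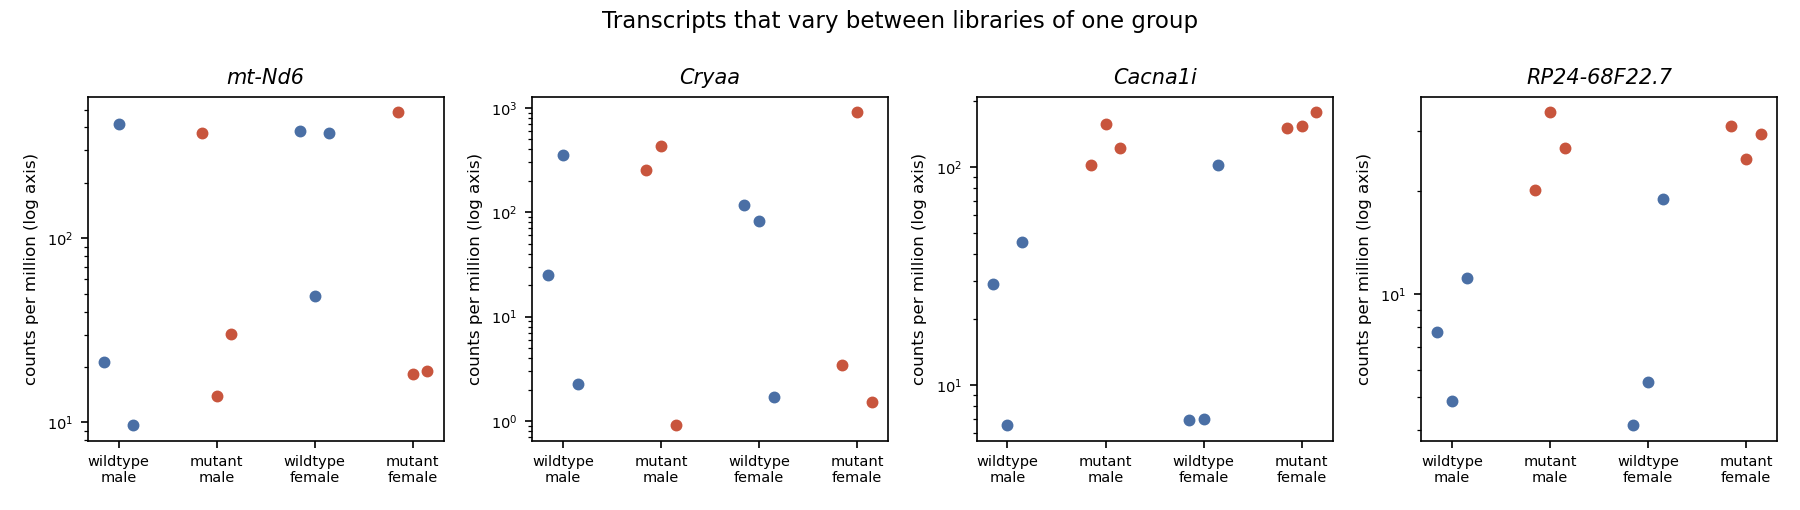
Expression in CPM (log axes) of mt-Nd6, Cryaa, Cacna1i and RP24-68F22.7 in each library of the 4 groups, 1 point per library. Wildtype Cacna1i runs from 6.56 to 102 CPM, and Cryaa from 0.918 to 907 CPM over all libraries.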

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

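The test of the single gene Eomes without adjustment over all genes was chosen after its p had been seen. The log2 genotype effect on Eomes in females minus that in males was -0.64, a larger fall in females (SE 0.25, edgeR quasi-likelihood interaction, unadjusted p = 0.0264), a difference between groups that did not pass over all genes (adjusted p = 1.0). All 100 of 100 splits of the libraries drawn within sex reached the real count of 0 interaction genes, as any split must, so these splits decide nothing about chance. The highest of the others called 625, which points to a structure of the samples. That split put both males high in mt-Nd6 on the same side and all 3 such females on the other, so it followed the mt-Nd6 set.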

How the results depend on the processing

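The fits with a library batch term or within the mt-Nd6 sets, with robust empirical Bayes, with sample quality weights, with Cryaa, and with mutant male 6 or the libraries highest in Cryaa left out, and the estimated correlation outside the full fit, were chosen after the results were seen. Over 29 alternatives for both sexes the log2 fold change of Eomes stayed between -2.12 and -1.50 and past the threshold in 28 (adjusted p from 2.53e-26 to 0.131, DESeq2 and edgeR included), and the median of the ipRGC list between -0.55 and -0.17 in 19 of 19, though its call was lost with an estimated correlation within both mt-Nd6 sets and without mutant male 4 or mutant female 4. The count of 4 genes in both sexes became 15 with DESeq2, 2 with at least 1 CPM in 3 libraries, 1 at an adjusted p under 0.01, 2 without the sex term, 9 with the library batch term, 10 with that term and mutant male 6 left out, 10 with voom quality weights, 2 with Cryaa as covariate, and 0 by edgeR with the 3 libraries highest in Cryaa left out (251 at an unadjusted p under 0.05). The count of 0 in males became 6 with DESeq2, 2 with the batch term and 8 with quality weights. The count of 1 in females became 9 with DESeq2, 0 by edgeR at an adjusted p under 0.01 (394 at an unadjusted p under 0.05), 0 with Cryaa (532 likewise), and 62 and 61 within the sets high and low in mt-Nd6, each of 3 libraries with 1 genotype held by a lone library, and with Cryaa and other lens genes called in the low set. The interaction went from 0 to 2 within the high set, where 3 of 4 groups held 1 library. Female against male wildtype went from 1 to 2 with DESeq2, 3 with quality weights and 4 within the high set, which held 1 wildtype male; lone libraries were assumed to vary like the others. The list count went from 1 to 2 with the batch term (lens added, adjusted p = 0.0478, but adjusted p = 0.713 and a count of 1 with that term and an estimated correlation), 9 within the high set and 3 within the low set. Leaving out each library gave 1 to 5 genes in both sexes, 0 to 2 in females, 0 in males and for the interaction, 1 to 2 for female against male wildtype, and 1 to 6 lists. With the replicate block the counts were 1 in both sexes (Eomes, with Trhde, Synm and Wnt4 not called), 2 in females and 3 lists (amacrine and lens genes added), the block changed no other count, Ebf3 no longer passed over its list alone, and with an estimated correlation the ipRGC list was at adjusted p = 0.0878. In males the numbers did not pair the libraries, and among females 4 and 5 pairing cannot be told apart from the mt-Nd6 set. Small differences reversed for Pou4f2 (0.0116 within the high set), Isl1 (0.0500 within the high set, and 0.00579 with the batch term and mutant male 6 left out) and Pou4f1 (0.00801 within the low set), none past the threshold. Where fewer libraries or a stricter threshold was not itself the change, the cause was not tested. Over the genes followed and the ipRGC list, 1352 values kept direction and side of the threshold, 63 passed it newly, 53 no longer passed it and 4 reversed. The 1352 include values that passed in neither fit, so they do not measure how stable the calls were. In both sexes Trhde had an adjusted p under 0.05 in 20 of 29 alternatives, Synm in 12 of 29 and Wnt4 in 12 of 28. Depth limits Wnt4, at 0 to 6 counts per mutant library.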

Other observations

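All tests in this part were chosen after the results were seen, except the counts of splits and the test of GC content and length. Shh, a secreted signal made by ganglion cells, was at 4.09 ± 1.12 CPM in wildtype and 6.05 ± 0.530 CPM in mutants (n = 6 each), higher in 6 of 6 mutant libraries than in all wildtype libraries of the same sex. Its log2 difference of 0.56 (SE 0.18, edgeR unadjusted p = 0.00689) did not pass over all genes (adjusted p = 0.918), and was 0.40 and 0.90 within the sets high and low in mt-Nd6. Over all genes tested, 61 (0.394%) separated the genotypes the same way in both sexes, as Shh did, against 0.5% by chance. This separation alone is therefore no sign of a change.

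Chance was tested by other splits of the libraries within sex. For both sexes 3 of 100 splits called at least 4 genes, the real one included. The remaining splits called 0 genes, so a real count of 1 would have given the same share. At that share chance can be excluded for having any call, which Eomes, the targeted gene, would give alone. The splits do not exclude chance for Trhde, Synm or Wnt4. The highest others called 2555 and 940, and both put all 5 libraries high in mt-Nd6 on the same side, which points to a structure of the samples. For males all 10 of 10 splits reached the real count of 0, as any split must, with the highest other at 8, so they decide nothing. Among females 2 of 10 reached the real 1, the other calling 1428 and following the mt-Nd6 set, and for female against male wildtype 2 of 10 reached 1, the highest other being 1. Splits of 6 libraries are too few for a share under 0.05. For the gene lists 77 of 100 splits called at least 1 list, the highest other 9, so chance cannot be excluded for that count. The ipRGC list itself was called in 13 of 100 splits at the preset correlation, and in 1 of 100, the real one, with an estimated correlation. Apart from the real one, each of these 13 splits put 4 or 5 mutant libraries on the same side. They carry part of the genotype contrast and give no rate of chance calls.

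Between the 5 libraries high in mt-Nd6 and the other 7, edgeR called 2057 genes, 1759 higher and 298 lower in the 5. Of 12 mitochondrial genes 10 were higher, with a median log2 difference of 1.05 over the 12. These include mt-Nd6 itself (4.15), whose rise is fixed because its level defined the sets. All 4 groups held libraries of both sets, which argues against genotype or sex as the source. Replication-dependent histone genes, which lack a poly(A) tail, had a median of -0.24, which argues against less strict selection of polyadenylated RNA. Antisense genes had a median of -0.0614, which argues against counting on the opposite strand for those genes as a set. It does not settle the strand for mt-Nd6, which rose by 4.15 against 1.41 for mt-Nd1, as the strand setting is unknown. A trend on GC content and length explained 41.4% of the variance among the genes that differ, between the bounds set in advance, so a GC-dependent difference in library preparation may account for part and cannot be told apart from other differences in preparation.

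Cacna1i, a T-type calcium channel gene, was at 102 to 179 CPM in mutant libraries, and in wildtype at 29.0, 6.56 and 45.2 CPM in males 4, 5 and 6 and at 6.91, 6.96 and 102 CPM in females 4, 5 and 6. Loss of Eomes is argued against for this spread, since the lowest wildtype Eomes level was 1.95 times the highest mutant level, and so is the mt-Nd6 set, with a log2 difference of -0.0537 (SE 0.63). Over the 6 wildtype libraries Cacna1i followed RP24-68F22.7, an antisense gene inside the span of Six3 (Spearman rho 0.943, exact permutation p = 0.0167, adjusted p = 0.0333 over 2 relations, and Pearson r of log2 levels 0.972, exact permutation p = 0.00417, adjusted p = 0.00833). Without the 2 libraries farthest from the median r was 0.895. A candidate explanation is that some pools labelled wildtype held retinas with the Six3-Cre transgene, which stays open, as no read of Cre was analysed here.

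Lens transcripts varied between libraries of the same group, with Cryaa at 0.918 to 907 CPM. Over the 6 wildtype libraries 14 other lens genes followed Cryaa, with a median Spearman rho of 0.943 (0.714 to 1), as carry-over of lens tissue would give. Genotype is the same within a group and is by design no source of that spread. Whether genotype also shifts the mean stays open: the mutant minus wildtype difference of log2(CPM + 1) of Cryaa was 0.23 beside a permutation SD of 2.03 (two-sided exact permutation within sex, p = 0.95). The edgeR fit on counts, which weighs the libraries with the highest levels more, gave 1.48 (SE 1.48, adjusted p = 0.918).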
